A study of Mus musculus with 6 samples.

How the data were processed

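The samples were 6 cultures of mouse CD4-positive, CD25-negative T cells, 2 per coating. Per the labels' protocols, CD25-positive cells were removed with an antibody and magnetic beads, CD4-positive cells were then selected with beads, and the cells were cultured for 4 days with TGF-beta and IL-2. Per the labels' protocols, 50 ng of total RNA was amplified with a NuGen Ovation system and labelled with biotin, and each culture was hybridised to 1 array. This amplification can change the relative signal of transcripts, equally for all 6 arrays as far as the labels say.

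The deposited values are probe set intensities on a linear scale, processed with RMA per the submitters' processing notes. RMA corrects background, normalizes the arrays to each other and summarises the probes of a set. The version, the software and the chip definition are not given in the sources used here. The design had assumed log2 values; the values themselves showed a linear scale, and as foreseen all values were log2 transformed before any test. RMA makes the distributions of the arrays alike, so a change common to most transcripts would not be seen. It also compresses changes of dim probe sets: the median intensity was 18.4 to 18.8 and the median of the nonspecific control probe sets was 3.68 to 4.49, so changes of dim genes rest on signal close to background.

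The table held 45141 probe sets, of which 104 were controls. By the platform annotation, 28898 had 1 gene symbol, 551 had several and 15588 had none; the last number counts probe sets unnamed here. Symbols were updated by Entrez identifier for 28689 probe sets with the GRCm38.p6 gene table, used only for names. Each gene was represented by the probe set of highest mean over the 6 arrays, which gave 17097 genes, with no filter on dim genes. Where a gene had several probe sets, they were compared. Of the called genes, 27 in the B7-2 comparison (0.644%), 11 in the BTNL2 comparison (0.316%) and 23 in the comparison of BTNL2 wells with anti-CD3 alone (0.443%) had probe sets called in opposite directions. No genomic coordinates are given because the files name no genome build.

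Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with all 6 arrays in 1 fit, 3 residual degrees of freedom and 4.02 prior degrees of freedom, without a block for replicate number. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 17097 genes of a comparison were called, and a fold is 2 to the power of the log2 change. The smallest fold called was 1.21, 1.23 and 1.20 in the 3 comparisons. Before the data were examined, 27 gene lists with 556 genes were fixed, of which 495 genes were measured under a probe set with 1 symbol. Each list was tested with limma's camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 27 lists of the comparison, with an estimated correlation and limma's fry beside it. Members of a list were also adjusted over the list alone.

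Named genes followed a rule fixed together with the lists. In each comparison they were the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between groups, leaving out symbols of predicted genes and clones. For BTNL2 against B7-2 the 4 members of each list with the smallest p were added, and in the other comparisons the 3 of each called list. Foxp3, Il2ra, Ctla4, Il2, Ifng, Il10, Foxo1, Klf2, Cd4 and Cd8a were followed in every comparison, and the other genes of that set were not analysed here.

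The procedure was tested on simulated data with 200 changed genes among 17097. For the B7-2, the BTNL2 and the third comparison, 76.1%, 74.6% and 80.6% of 1.5-fold changes were recovered, and 98.5%, 98.5% and 97% of 2-fold changes. False calls made up 6.63%, 7.61% and 6.09% of the calls, slightly more than the nominal 5%. The simulated noise was independent between genes. In the data far more genes were called, from 20.4% for BTNL2 against B7-2 to 30.4% in the third comparison. These shares therefore need not hold for the data. Alternatives changed the variance prior (intensity trend, robust), the arrays in the fit, the filter on dim genes (below the 40th percentile of all probe sets), the scaling (quantile normalization again, median centring), the probe sets per gene (mean, or each tested), the replicate block, the correlation between genes and each array in turn. The opposed changes of the B7-2 and BTNL2 comparisons were set beside 100 simulated data sets with unchanged BTNL2 wells.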

Results

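Messenger RNA was measured on 6 one-colour oligonucleotide arrays from cultured mouse T cells. The cells were CD4-positive, CD25-negative T cells from female C57BL/6 mice, so cells already carrying the IL-2 receptor alpha chain, among them most regulatory T cells, had been removed beforehand. They were cultured for 4 days on plates coated with proteins that engage receptors on T cells. In the first group the plate carried an antibody to CD3, which triggers the T cell receptor, at 2 µg/ml with control IgG. In the second group it also carried B7-2 (CD86), the costimulatory ligand of CD28 and CTLA-4, at 3 µg/ml as an Fc fusion protein. In the third group BTNL2, a butyrophilin-like relative of the B7 family, was added to anti-CD3 and B7-2 at 11 µg/ml as an Fc fusion protein. All wells held TGF-beta at 0.36 ng/ml and IL-2 at 10 ng/ml. The groups are called the anti-CD3, B7-2 and BTNL2 wells here, and each has 2 arrays. One label gives spleen as the source of the cells and another gives spleen and lymph nodes.

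The labels say that cultures were in duplicate, and nothing says that duplicates came from separate animals. The p-values therefore measure only the spread between these cultures and their arrays. Duplicates of a group correlated at r = 0.997 to 0.998 across the 17097 genes tested, and arrays of different groups at 0.974 to 0.987. Genes are not independent replicates in these correlations. The first principal component held 60.8% of the variance and set the BTNL2 wells apart, and the second held 29.5% and set the B7-2 wells apart. Median intensity was 18.4 to 18.8 on the 6 arrays. The ratio of 3' to 5' signal for beta-actin, a measure of RNA integrity, was 1.67 to 1.92. The same ratio for Gapdh was 1.40 and 1.43 on the BTNL2 arrays and 1.27 to 1.37 on the other 4. The 18S ribosomal RNA probe read 683 on the second anti-CD3 array and 1308 to 2019 on the others. The number of arrays, 2 per group, limits the precision of every value. Errors are standard errors of the log2 change from the limma fit unless given as SD, with n = 2 arrays per group throughout.

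The first comparison asks what B7-2 costimulation added to anti-CD3 alone. Cytokine genes were among the largest rises. Il9 was 15.8-fold higher in the B7-2 wells (log2 change 3.98 ± 0.21, adjusted p = 0.000166) and Il5, the eosinophil growth factor gene, 14.9-fold higher (log2 change 3.89 ± 0.23, adjusted p = 0.00018). Il10 rose 7.35-fold, from a mean intensity of 86.7 ± 10.6 to 635 ± 26 (SD, n = 2), and Ifng 4.78-fold, from 264 ± 31.3 to 1255 ± 56 (SD, n = 2). Ctla4, the inhibitory B7 receptor, rose 1.54-fold (log2 change 0.62 ± 0.10, adjusted p = 0.00427). Foxp3, the defining transcription factor of regulatory T cells, read 87.6 ± 12.5 and 73.9 ± 5.15 (SD, n = 2) and did not pass the test (log2 change -0.24 ± 0.12, adjusted p = 0.209).

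Of 17097 genes, 1909 were higher and 2281 lower in the B7-2 wells at a limma adjusted p under 0.05, a total of 4190, of which 207 and 456 changed at least 2-fold. At an unadjusted p under 0.05 the total was 6030. The other largest rises were of Pth (16.3-fold), Ccl3 (8.7-fold), Nts (8.13-fold), Dclk1 (7.62-fold), Sval1 (7.4-fold), Pde1a (7.26-fold) and Ermn (6.61-fold). The largest falls were of Gucy1a1 (14.5-fold), Tbc1d30 (11.4-fold), Trib2 (10-fold), Pglyrp1 (9.96-fold), Slfn1 (9.84-fold), Calhm6 (8.71-fold), Npas2 (7.9-fold), Tgfb3 (7.46-fold), Csf1 (7.23-fold) and Fam183b (6.99-fold). Several of these folds depended on the choice of probe set: averaged over all probe sets of a gene, the log2 change was -2.10 for Gucy1a1, -1.99 for Tbc1d30, -1.90 for Trib2, -1.58 for Npas2, 1.75 for Dclk1 and 1.37 for Pde1a, against -3.86, -3.52, -3.32, -2.98, 2.93 and 2.86. The log2 change of Tgfb3, -2.90, was -3.51 without the first B7-2 array and -2.28 without the second. Among the other genes followed throughout, Il2ra (log2 change 0.11 ± 0.08, adjusted p = 0.431), Il2 (log2 change 0.43 ± 0.21, adjusted p = 0.207), Foxo1 (log2 change -0.21 ± 0.17, adjusted p = 0.454), Klf2 (log2 change -0.41 ± 0.14, adjusted p = 0.0817) and Cd4 (log2 change -0.26 ± 0.09, adjusted p = 0.0949) did not pass. Without the second B7-2 array Klf2 was called lower (log2 change -0.61, adjusted p = 0.0231), and with an intensity trend in the variance prior Cd4 was called lower. The count of called genes was 2454 without the first anti-CD3 array, 2647 without the second, 2722 without the first B7-2 array and 2687 without the second.

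Genes of ribosome biogenesis, the amino acid response and DNA replication rose. Those of cholesterol synthesis did not, with 1 higher and 1 lower of 19 (camera adjusted p = 0.637). Of 25 ribosome biogenesis genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 0.79 (camera adjusted p = 1.06e-15, and adjusted p = 0.0858 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, rose 2.59-fold, the pseudouridine synthase gene Dkc1 2.38-fold and Utp20 2.28-fold. Of 25 genes of the amino acid response, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 4.29e-11, and adjusted p = 0.0858 with an estimated correlation), among them Sesn2 (3.05-fold), Trib3 (2.28-fold) and Atf3 (2.17-fold). Of 32 DNA replication genes, 23 rose and 0 fell (29 and 1 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.82e-11, and adjusted p = 0.394 with an estimated correlation), and Rrm2, a subunit of ribonucleotide reductase, rose 1.96-fold, Cdc6 1.76-fold and Ccne2 1.65-fold.

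Weaker list changes lay close to the threshold. Among 28 mitosis genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0451, and adjusted p = 0.487 with an estimated correlation), and Cdc20 rose 1.58-fold and Aurka 1.47-fold. Among 20 IL-2 and STAT5 response genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0451, and adjusted p = 0.423 with an estimated correlation), and the lymphotoxin gene Lta rose 4.04-fold and Lif 2.86-fold (log2 change 0.65 with the mean of its probe sets). Among 19 p53 response genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0451, and adjusted p = 0.394 with an estimated correlation), and Perp rose 3.86-fold while the death receptor gene Fas fell 2.1-fold. After median centring of the arrays each of these 3 lists had a camera adjusted p of 0.051 and was not called. After a repeated quantile normalization their adjusted p was 0.081 for mitosis, 0.0632 for IL-2 and STAT5 and 0.0502 for p53.

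Interferon-stimulated and resting-cell genes fell. Of 26 interferon-stimulated genes, 0 rose and 16 fell (0 and 16 adjusted over the list alone), with a median log2 change of -0.56 (camera adjusted p = 1.28e-07, and adjusted p = 0.394 with an estimated correlation). Gbp2 fell 5.59-fold (log2 change -2.48 ± 0.09, adjusted p = 6.99e-05), Gbp3 4.02-fold and Usp18 3.71-fold. Of 17 genes of naive T cells, 3 rose and 11 fell (4 and 12 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.000857, and adjusted p = 0.394 with an estimated correlation), and Rgs10 fell 3.68-fold, Igfbp4 3.27-fold and the transcription factor gene Bach2 2.45-fold. Of 16 genes induced by the transcription factor Foxo1, 3 rose and 9 fell (3 and 10 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00109, and adjusted p = 0.43 with an estimated correlation), and Bcl6 fell 5.47-fold, the pro-apoptotic gene Bcl2l11 3.89-fold and Sesn3 2.53-fold. The log2 change of Bcl6, -2.45, was -1.30 with the mean of its probe sets.

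Markers of other cell types fell alongside. Of 16 B cell markers, 0 rose and 9 fell (0 and 10 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 9.82e-05, and adjusted p = 0.423 with an estimated correlation), among them the antigen receptor subunit gene Cd79b (2.47-fold) and the MHC class II genes H2-Aa (2.51-fold) and H2-Eb1 (2.35-fold). Of 12 markers of CD8 T cells and NK cells, 0 rose and 5 fell (1 and 5 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0159, and adjusted p = 0.394 with an estimated correlation). Cd8a, the CD8 alpha chain gene, fell 2.76-fold, from 311 ± 13.3 to 113 ± 8.78 (SD, n = 2), Klrd1 3.74-fold and Crtam 1.98-fold.

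The remaining 16 lists were not called in this comparison. Th2 genes came closest among lineage lists, with 8 of 16 higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.0679). Of 18 Th1 genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.196), and of 25 regulatory T cell genes, 5 and 5 (6 and 8 adjusted over the list alone, camera adjusted p = 0.637). Median and mean differed in sign for Th1 genes (-0.05 and 0.48, with the test upward) and for regulatory T cell genes (-0.04 and 0.02, with the test downward). The camera calls use a preset correlation of 0.01 between genes. With the correlation estimated from the arrays, 0 of the 27 lists were called in this or in either other comparison, and 2 of 27 had an unadjusted p under 0.05 in this one. By limma's fry, which asks whether the genes of a list move on balance in 1 direction, 16 of the 27 lists were called.

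The second comparison asks what BTNL2 changed in cells that also received B7-2. Foxp3 rose 4.1-fold, from 73.9 ± 5.15 to 303 ± 4.65 (SD, n = 2; log2 change 2.04 ± 0.12, adjusted p = 6.59e-05). Chemokine genes and the gene of the T-box factor Eomes, which drives cytotoxic programmes, showed the largest rises: Xcl1 231-fold, from 6.8 ± 1.12 to 1572 ± 297, Ccl1 95.1-fold, from 26.9 ± 0.255 to 2574 ± 442, and Eomes 63.8-fold, from 18.1 ± 2.6 to 1164 ± 245 (SD, n = 2). The Xcl1 signal of the B7-2 wells lay near that of the nonspecific controls, whose medians were 3.68 to 4.49. Ctla4 fell 3.14-fold (log2 change -1.65 ± 0.10, adjusted p = 6.62e-05), Il10 2.58-fold (log2 change -1.37 ± 0.16, adjusted p = 0.00135), Il5 16.2-fold (log2 change -4.02 ± 0.23, adjusted p = 5.92e-05) and Il21 18.9-fold (log2 change -4.24 ± 0.28, adjusted p = 0.000107, or -3.36 with the mean of its probe sets). Ifng rose 2.16-fold (log2 change 1.11 ± 0.12, adjusted p = 0.000837), and Cd8a, a marker of another T cell lineage, rose 8.48-fold, from 113 ± 8.78 to 955 ± 44.1 (SD, n = 2).

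**Figure D1:**
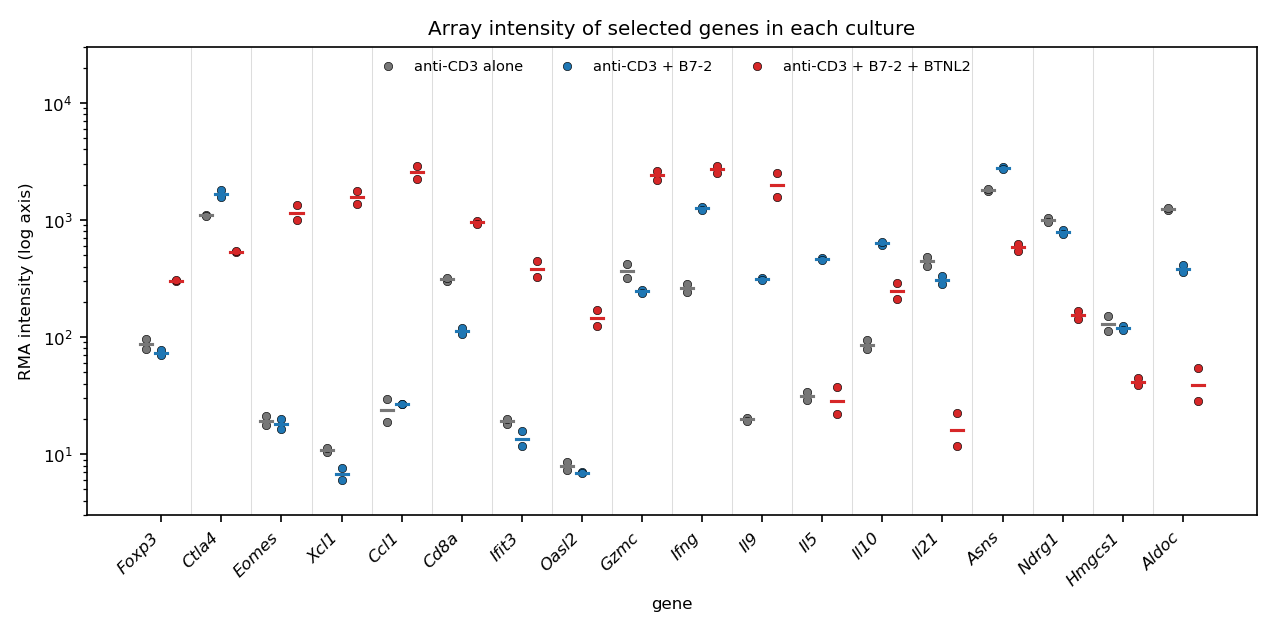
RMA intensity on a log axis for 18 genes in each of the 6 cultures, with points for single arrays, bars for the geometric mean of the 2 arrays and colours for the 3 groups. In the BTNL2 wells Foxp3 has a mean of 303, against 73.9 with B7-2 and 87.6 with anti-CD3 alone, and Xcl1 has 1572, against 6.8 and 10.9.

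In all, 1628 genes were higher and 1854 lower in the BTNL2 wells at a limma adjusted p under 0.05, a total of 3482 of 17097, of which 427 and 461 changed at least 2-fold and 116 and 113 at least 4-fold. At an unadjusted p under 0.05 the total was 5534. The other largest rises were of Trgv1, a T cell receptor gamma variable segment (49.4-fold), Ms4a4b (33.2-fold), the interferon-inducible genes Ifi205 (32.6-fold), Ifit1bl1 (28.7-fold), Ifit3 (28.1-fold) and Ifit1 (28-fold), and Cdh1, the E-cadherin gene (28.5-fold). The other largest falls were of Stfa2l1 (59-fold), the glutamate transporter gene Slc17a6 (42.5-fold), Pth (38.3-fold), Inhba, which encodes an activin subunit (32.3-fold, or a log2 change of -2.55 with the mean of its probe sets), Selenbp2 (22.8-fold), the cationic amino acid transporter gene Slc7a3 (22.4-fold), Timp1 (18-fold) and Serpinf1 (16.9-fold). With the mean of the probe sets the log2 change was 2.93 for Ms4a4b, -2.90 for Serpinf1 and -4.82 for Slc17a6, against 5.05, -4.08 and -5.41. Without the first or the second BTNL2 array it was -4.75 and -6.07 for Slc17a6, -3.47 and -4.70 for Serpinf1 and 4.23 and 5.43 for Cdh1, against 4.83 for Cdh1 with all arrays. Klf2, a transcription factor gene of resting T cells, rose 2.08-fold (log2 change 1.06 ± 0.14, adjusted p = 0.00229), while Il2ra (log2 change -0.16 ± 0.08, adjusted p = 0.253), Il2 (log2 change 0.29 ± 0.21, adjusted p = 0.417), Foxo1 (log2 change 0.18 ± 0.17, adjusted p = 0.533) and Cd4 (log2 change -0.27 ± 0.09, adjusted p = 0.0935) did not pass. With the mean of all probe sets of a gene, and with an intensity trend in the variance prior, Il2ra and Cd4 were called lower. Without the first B7-2 array the count of called genes was 2181, without the second 2313 and without the first BTNL2 array 2142.

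Interferon-stimulated genes rose with BTNL2. Of 26 measured, 21 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 change of 1.36 (camera adjusted p = 4.83e-19, and adjusted p = 0.171 with an estimated correlation). Oasl2 rose 20.9-fold (log2 change 4.38 ± 0.16, adjusted p = 1.15e-05), Isg20, an antiviral exonuclease gene, 13.9-fold (log2 change 3.80 ± 0.10, adjusted p = 4.76e-06), and Irf7, the transcription factor gene of the type I interferon response, 4.75-fold (log2 change 2.25 ± 0.10, adjusted p = 2.2e-05). B cell markers, of which several are MHC class II genes, also rose. Among 16 measured, 8 were higher and 2 lower (11 and 2 adjusted over the list alone). The median was 0.48 (camera adjusted p = 0.000704, and adjusted p = 0.375 with an estimated correlation). Ms4a1 (CD20) rose 3.4-fold, H2-Aa 2.4-fold and H2-Eb1 2.24-fold, while the B cell transcription factor gene Ebf1 fell 2.7-fold.

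Genes of Th1 cells and of cytotoxic granules rose, and most Th2 genes that changed fell. Of 18 Th1 genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.000143, and adjusted p = 0.171 with an estimated correlation), among them Ccl3 (3.6-fold), Il18rap (5.35-fold) and Cxcr6 (2.91-fold). Of 15 cytotoxic granule genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 7.7e-05, and adjusted p = 0.171 with an estimated correlation). The granzyme genes Gzmc, Gzma and Gzmk rose 9.78-fold, 2.71-fold and 2.77-fold, and Ctsw, a protease gene of cytotoxic cells, 7.04-fold. Of 16 Th2 genes, 3 rose and 9 fell (3 and 10 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.0149, and adjusted p = 0.375 with an estimated correlation). Il24 fell 4.86-fold and Il13 2.65-fold, whereas Il9 rose a further 6.36-fold (log2 change 2.67 ± 0.21, adjusted p = 0.000202).

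Markers of CD8 T cells and NK cells rose in the same wells. Of 12 measured, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 change of 1.5 (camera adjusted p = 3.47e-08, and adjusted p = 0.116 with an estimated correlation). Besides Cd8a and Eomes, Crtam rose 7.8-fold and Klrd1 (CD94) 5.67-fold. Cd8b1, the CD8 beta chain gene, is a member of this list, which was fixed beforehand. It is named here outside the rule, after the change of Cd8a had been seen. Cd8b1 rose 2.49-fold, from 36.3 ± 7.86 to 89.1 ± 3.85 (SD, n = 2). Cd4 read 1363 ± 61.5 in the B7-2 wells and 1131 ± 39.4 in the BTNL2 wells (SD, n = 2).

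The list of regulatory T cell genes went both ways and was not called by camera, although fry called it (adjusted p = 0.0124). Of 25 measured, 12 rose and 7 fell (12 and 7 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.249). With Foxp3, Nt5e (CD73), an ectoenzyme that makes adenosine, rose 4.7-fold (log2 change 2.23 ± 0.13, adjusted p = 5.92e-05) and Fgl2, a gene of a suppressive secreted protein, 3.13-fold (log2 change 1.64 ± 0.11, adjusted p = 0.000119), while Ctla4 fell. Averaged over all probe sets of a gene, the log2 change was 0.85 for Nt5e and 0.86 for Fgl2. TGF-beta response genes rose: 10 of 17 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 8.87e-05, and adjusted p = 0.316 with an estimated correlation). The receptor gene Tgfbr1 rose 3.49-fold, Id3 2.72-fold, and the pathway inhibitor genes Ldlrad4 9.87-fold and Smurf1 1.77-fold. The log2 changes of Ldlrad4 and Tgfbr1, 3.30 and 1.80, were 2.35 and 0.93 with the mean of their probe sets. Of 17 naive T cell genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.00112, and adjusted p = 0.316 with an estimated correlation), and Nsg2 rose 7.77-fold, Foxp1 2.29-fold and Igfbp4 2.28-fold.

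Metabolic gene groups fell with BTNL2. Of 25 amino acid response genes, 0 rose and 19 fell (0 and 22 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 9.14e-12, and adjusted p = 0.116 with an estimated correlation). Asns, the asparagine synthetase gene, fell 4.74-fold (log2 change -2.25 ± 0.10, adjusted p = 2.45e-05), Nupr1 5.59-fold and Atf3 4.57-fold. Of 20 hypoxia response genes, 0 rose and 15 fell (1 and 16 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 1.5e-08, and adjusted p = 0.316 with an estimated correlation), and Stc2 fell 8.23-fold, Ndrg1 5.12-fold and Vegfa 3.11-fold. Of 19 glycolysis genes, 0 rose and 8 fell (0 and 13 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 9.39e-06, and adjusted p = 0.375 with an estimated correlation). The aldolase gene Aldoc fell 9.79-fold, the glucose transporter gene Slc2a3 4.46-fold and the hexokinase genes Hk1 and Hk2 1.61-fold and 1.52-fold. The log2 changes of Aldoc and Slc2a3, -3.29 and -2.16, were -1.99 and -1.54 with the mean of their probe sets. Of 19 cholesterol synthesis genes, 0 rose and 13 fell (0 and 15 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 1.79e-05, and adjusted p = 0.344 with an estimated correlation), and Hmgcs1 fell 2.87-fold and Fdft1 1.99-fold.

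Mitosis genes rose slightly. Of 28 mitosis genes, 7 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00228, and adjusted p = 0.395 with an estimated correlation), and Prc1 rose 1.41-fold and Plk1 1.32-fold. Prc1 was not called without the first B7-2 array (adjusted p = 0.0531). Plk1 was not called without the first or the second B7-2 array (adjusted p = 0.0781 and 0.094) or without the second BTNL2 array (adjusted p = 0.0887). Of 32 DNA replication genes, 2 rose and 1 fell, with a median of 0.03 (0 and 0 adjusted over the list alone, camera adjusted p = 0.293). Of 25 ribosome biogenesis genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.293), and of 29 genes of oxidative phosphorylation, 0 rose and 2 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.89). None of these 3 lists was called.

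Several of the other lists that were not called held members that changed in both directions. Among 22 T cell activation genes, 5 rose and 10 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.249), with the orphan receptor gene Nr4a3 4.24-fold higher (log2 change 0.70 with the mean of its probe sets) but its relatives Nr4a2 and Nr4a1 2.52-fold and 1.89-fold lower, Nr4a2 with a log2 change of -0.67 with the mean of its probe sets. Among 19 co-inhibitory and anergy genes, 6 rose and 8 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.723), with Cd160 6.44-fold higher and Cd200 3.83-fold lower. Among 13 genes of follicular helper T cells, 3 rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.0676), with Btla 2.74-fold lower and Slamf6 2.48-fold higher. Among 26 homing receptor and integrin genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0548, 0.0472 after median centring and 0.0577 after a repeated quantile normalization), with Itgb3 4.43-fold and Itga6 3.3-fold higher. Among 16 Foxo1-induced genes, 3 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.071), with Bcl2l11 6.94-fold higher and Gadd45a 4.6-fold lower.

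Among 20 IL-2 and STAT5 response genes, 3 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.249), with Prdm1 (Blimp-1) 2.27-fold lower. Among 12 Th17 genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.677), with Tmem176b 2.65-fold higher. Among 19 p53 response genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.957), with Fas 2.07-fold higher and Perp 2.52-fold lower. Of 21 myeloid cell markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.214), with Fcer1g 3.2-fold and Ctss 2.01-fold higher, and of 11 erythroid and platelet markers, 1 rose and 0 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.557), the 1 being Car2 (4.63-fold). Median and mean differed in sign for the co-inhibitory list (0.12 and -0.05, with the test downward) and for p53 response genes (0.02 and -0.08, with the test upward). With an estimated correlation 0 of the 27 lists were called and 5 had an unadjusted p under 0.05, and fry called 19. The fry calls included lists that camera did not call, such as regulatory T cell genes (fry adjusted p = 0.0124) and myeloid cell markers (fry adjusted p = 0.0145).

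**Figure D2:**
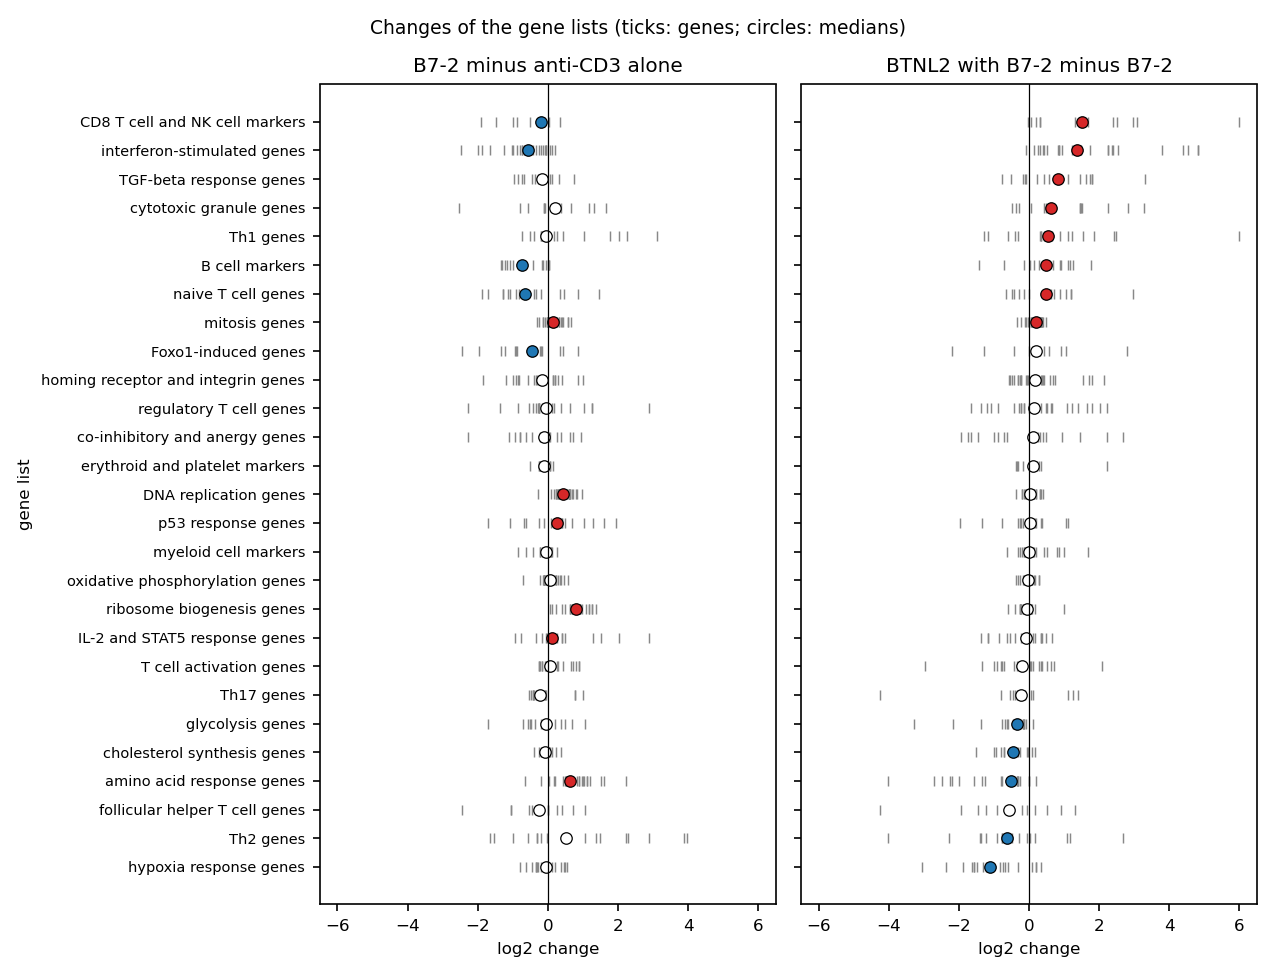
Log2 change of the measured genes (ticks) of the 27 gene lists with their medians (circles), for B7-2 minus anti-CD3 alone on the left and BTNL2 with B7-2 minus B7-2 on the right; filled circles mark lists called by camera with the preset correlation, red upward and blue downward. Interferon-stimulated genes have a median of -0.56 on the left and 1.36 on the right, and amino acid response genes 0.63 and -0.52.

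Many genes that B7-2 had changed moved the opposite way with BTNL2, but the wells did not return to the anti-CD3 state. Across genes, BTNL2 arrays correlated with anti-CD3 arrays at r = 0.974 to 0.978, and B7-2 arrays at 0.986 to 0.987. Il5 rose 14.9-fold with B7-2 and fell 16.2-fold with BTNL2, and Slfn1, followed here as a large fall with B7-2, fell 9.84-fold and rose 9.07-fold. Il9 and Ccl3, large rises with B7-2, rose further with BTNL2 (log2 change 2.67 and 1.85). Among the 1909 genes higher with B7-2, 482 fell and 108 rose further with BTNL2, where independent lists would share 207 and 182. Among the 2281 lower with B7-2, 681 rose and 410 fell further, where independent lists would share 217 and 247. Of the 4190 genes called for B7-2, 2613 (62.4%, exact binomial 95% interval 60.9 to 63.8%, which treats genes as independent) changed in the opposite direction with BTNL2, called or not. Both comparisons use the same B7-2 arrays with opposite signs, and 100 simulated data sets with unchanged BTNL2 wells gave a mean of 58.3% (56.8 to 59.6%). BTNL2 changes nothing in these data sets, so hardly any gene can be called for it. Their count of genes called in both and opposed, at most 2, is therefore low by construction. The data held 1163 such genes, and 518 called in the same direction. The simulated share likewise holds chance values only, so its distance from 62.4% does not by itself show opposition. The covariance of both sets of log2 changes over all genes was -0.0585, the simulated mean was -0.0078 and the difference -0.0507. The correlation was -0.25, against a simulated mean of -0.14. In a test chosen after the results had been seen, a different B7-2 array was used in each comparison. The covariance was then -0.0528 and -0.0444 for the 2 ways of assigning the arrays, and the lowest simulated was -0.00226. This argues against chance values of single arrays as the whole of the excess. A difference common to both B7-2 wells stays open.

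**Figure D3:**
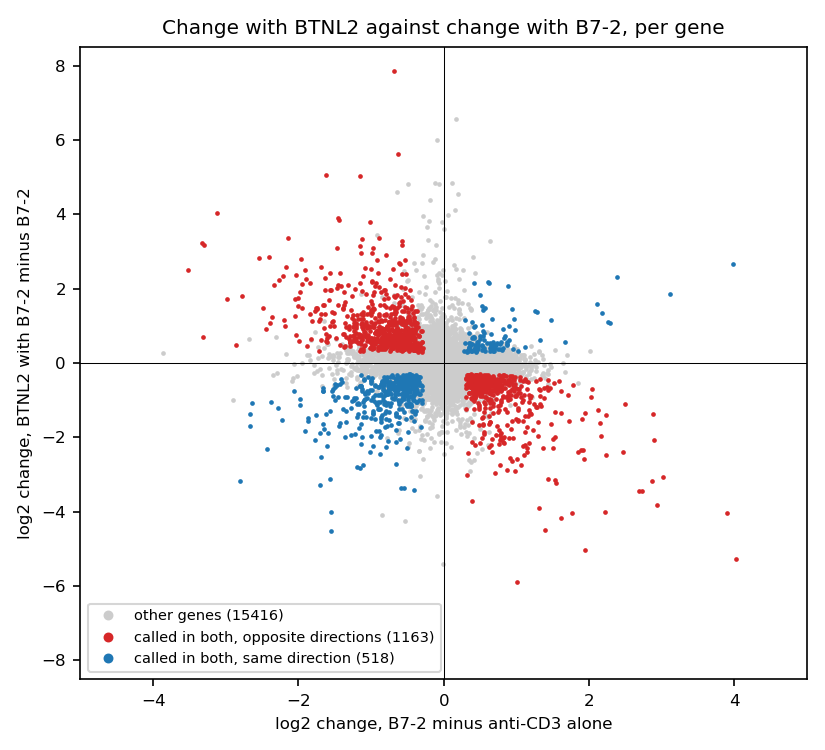
Log2 change of each of the 17097 genes with BTNL2 (vertical axis, BTNL2 with B7-2 minus B7-2) against its log2 change with B7-2 (horizontal axis, B7-2 minus anti-CD3 alone). Genes called in both comparisons are coloured, 1163 in opposite directions (red) and 518 in the same direction (blue).

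The third comparison sets the BTNL2 wells against anti-CD3 alone. Foxp3 was 3.47-fold higher in the BTNL2 wells (log2 change 1.80 ± 0.12, adjusted p = 7.92e-05), Ifng 10.3-fold (log2 change 3.37 ± 0.12, adjusted p = 8.7e-06) and Il10 2.85-fold (log2 change 1.51 ± 0.16, adjusted p = 0.000577). Ctla4 was 2.04-fold lower (log2 change -1.03 ± 0.10, adjusted p = 0.000326) and Cd4 1.44-fold lower (log2 change -0.53 ± 0.09, adjusted p = 0.00513), while Cd8a was 3.07-fold higher (log2 change 1.62 ± 0.10, adjusted p = 5.82e-05). Klf2 (1.57-fold, adjusted p = 0.0122) and Il2 (1.64-fold, adjusted p = 0.0418) were also higher, Il2 at a mean intensity of 21.8. Klf2 was not called without the second anti-CD3 array or the first BTNL2 array (adjusted p = 0.0751 and 0.0628). Il2 was not called with the replicate number as a block (limma adjusted p = 0.0544). It was also not called without the second anti-CD3 array or without the first or second BTNL2 array (log2 change 0.45, 0.89 and 0.54). Foxo1 (log2 change -0.03 ± 0.17, adjusted p = 0.933) and Il2ra (log2 change -0.05 ± 0.08, adjusted p = 0.718) did not pass. With the mean of all probe sets of a gene, Il2ra was called lower (log2 change -0.33).

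In this comparison 2422 genes were higher and 2775 lower, a total of 5197 by limma, of which 393 and 829 changed at least 2-fold, and 6641 had an unadjusted p under 0.05. The largest rises were of Xcl1 (143-fold), Ccl1 (107-fold), Il9 (100.3-fold), Eomes (59.7-fold), Trgv1 (32.1-fold), Ccl3 (31.3-fold), Cdh1 (30.8-fold), Ifit1 (26.8-fold), Rtp4 (26.5-fold) and Ifit1bl1 (26.3-fold). The largest falls were of Selenbp2 (66.7-fold), Fam183b (63.3-fold), Selenbp1 (46.9-fold), Slc17a6 (42.7-fold), Aldoc (31.8-fold), Serpinf1 (30.4-fold), Stfa2l1 (29.2-fold), Il21 (27.4-fold), Atp6v0d2 (26.9-fold) and the connexin gene Gja1 (25.9-fold). With the mean of the probe sets the log2 change was 2.73 for Rtp4, -3.72 for Aldoc, -3.73 for Gja1, -3.96 for Il21, -3.91 for Serpinf1 and -4.45 for Slc17a6, against 4.73, -4.99, -4.70, -4.77, -4.93 and -5.41. Without the first or the second BTNL2 array it was -4.76 and -6.07 for Slc17a6, -4.31 and -5.54 for Serpinf1 and 4.35 and 5.54 for Cdh1, against 4.95 for Cdh1 with all arrays.

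Growth genes were higher in the BTNL2 wells than with anti-CD3 alone. Of 25 ribosome biogenesis genes, 22 were higher and 0 lower (22 and 0 adjusted over the list alone; camera adjusted p = 1.64e-11, and adjusted p = 0.125 with an estimated correlation), with Ncl (nucleolin) 3.71-fold higher. Of 32 DNA replication genes, 25 were higher and 1 lower (28 and 1 adjusted over the list alone; camera adjusted p = 3e-10, and adjusted p = 0.332 with an estimated correlation), with Rrm2 2.08-fold higher, and of 28 mitosis genes, 15 and 0 (16 and 0 adjusted over the list alone; camera adjusted p = 2.27e-05, and adjusted p = 0.38 with an estimated correlation), with Plk1 1.78-fold higher. Hypoxia response genes were lower, 16 of 20 with 0 higher (1 and 16 adjusted over the list alone; camera adjusted p = 1.52e-07, and adjusted p = 0.35 with an estimated correlation), with Stc2 10.3-fold lower (log2 change -3.37, or -2.57 with the mean of its probe sets). Cholesterol synthesis genes were lower, 14 of 19 with 0 higher (1 and 15 adjusted over the list alone; camera adjusted p = 4.54e-05, and adjusted p = 0.38 with an estimated correlation), with Hmgcs1 3.13-fold lower. So were glycolysis genes, 11 of 19 with 3 higher (3 and 11 adjusted over the list alone; camera adjusted p = 0.00178, and adjusted p = 0.649 with an estimated correlation), with Slc2a3 6.23-fold lower.

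Immune gene groups moved as well. Of 26 interferon-stimulated genes, 14 were higher and 4 lower than with anti-CD3 alone (14 and 4 adjusted over the list alone; camera adjusted p = 0.000122, and adjusted p = 0.428 with an estimated correlation), with Ifit3 20-fold higher. Of 18 Th1 genes, 12 were higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 4.59e-05, and adjusted p = 0.125 with an estimated correlation), and of 15 cytotoxic granule genes, 11 and 1 (13 and 1 adjusted over the list alone; camera adjusted p = 3.4e-06, and adjusted p = 0.125 with an estimated correlation), with Gzmc 6.55-fold and the death ligand gene Fasl 4.71-fold higher. Markers of CD8 T cells and NK cells were higher beside them, 6 of 12 with 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 4.16e-05, and adjusted p = 0.125 with an estimated correlation), with Crtam 3.93-fold higher. Cd8b1, a member of this list, was not called (log2 change 0.43 ± 0.15, limma adjusted p = 0.0702). Of 17 TGF-beta response genes, 7 were higher and 1 lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00546, and adjusted p = 0.444 with an estimated correlation), with Cdkn2b 3.59-fold higher.

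Genes of follicular helper T cells were lower, 8 of 13 with 0 higher (1 and 8 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.25 with an estimated correlation), among them Bcl6 (2.88-fold, log2 change -1.53, or -0.88 with the mean of its probe sets) and Btla (3.76-fold). Co-inhibitory and anergy genes were lower on balance, 11 of 19 with 4 higher (4 and 11 adjusted over the list alone; camera adjusted p = 0.0421, and adjusted p = 0.332 with an estimated correlation), although Havcr2 (TIM-3) was 5.22-fold and Cd160 4.22-fold higher. With the replicate number as a block the count of called lists was 12 instead of 13, with 8 higher and 4 lower instead of 8 and 5. The regulatory T cell genes, 10 higher and 7 lower of 25 (12 and 8 adjusted over the list alone, camera adjusted p = 0.423), and the amino acid response genes, 7 and 8 of 25 (7 and 8 adjusted over the list alone, camera adjusted p = 0.777), were among the 14 lists not called. B cell markers (2 higher and 5 lower of 16, camera adjusted p = 0.428) were also not called. Median and mean differed in sign for Th2 genes (-0.21 and 0.32, test downward), for Th17 genes (0.20 and -0.26, test upward), for amino acid response genes (0.05 and -0.29, test downward) and for homing receptor and integrin genes (-0.05 and 0.06, test upward). They also differed for myeloid cell markers (-0.02 and 0.08, test upward) and for erythroid and platelet markers (-0.10 and 0.07, test downward). With an estimated correlation 0 of the 27 lists were called, 5 at an unadjusted p under 0.05, and fry called 17. The fry calls included regulatory T cell genes (fry adjusted p = 0.0249) and amino acid response genes (fry adjusted p = 0.0049), which camera did not call.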

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

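All tests in this part were chosen after the annotation of the probe sets had been seen. Probe sets without a single gene symbol entered none of the gene counts or lists of the report, and some changed. Of 16139 tested by limma, 2106 (13%) were called for B7-2 against anti-CD3 alone, 1089 higher and 1017 lower. For BTNL2 with B7-2 against B7-2, 1608 (9.96%) were called, 852 higher and 756 lower. For the BTNL2 wells against anti-CD3 alone, 2615 (16.2%) were called, 1432 higher and 1183 lower. Probe sets with 1 symbol were called more often, 19.7%, 16% and 25.6% in the same order. These transcripts without a symbol are unnamed here, and no explanation was tested.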

How the results depend on the processing

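The correlations of same-numbered arrays were not among the planned tests, and the counts of changes that shrank, moved or changed sign were chosen after the results had been seen; the alternatives were planned. The 243 named results were recomputed under 15 settings each, 3645 values in all: 3547 stayed on their side of the threshold, 67 lost the call and 31 gained it. No called result changed sign; 4 values of 3 results that were not called did, Foxo1 in both BTNL2 comparisons and Il2ra for B7-2, and they were not called under those settings either. Leaving out 1 array accounted for 51 of the 67 losses. With an estimated correlation, 0 lists were called for B7-2, 0 for BTNL2 and 0 for BTNL2 against anti-CD3 alone, in place of 11, 13 and 13. This setting takes the correlation from 3 residual degrees of freedom. Under all other settings 8 to 14 lists were called for B7-2, 12 to 15 for BTNL2 and 12 to 15 for the third comparison. The share of opposed changes was 60.8% with an intensity trend in the variance prior, in place of 62.4%, and the cause was not tested.

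Leaving out 1 array in turn gave 2454 to 4128 called genes for B7-2, 2142 to 3015 for BTNL2 and 3726 to 4870 for the third comparison, and opposed shares of 60.9% to 65.8%. Such a fit has fewer arrays, and the lone array of a group is assumed to vary like the other groups. For B7-2 the count was 2454 and 2647 without the first or second anti-CD3 array, and 2722 and 2687 without the first or second B7-2 array. For BTNL2 it was 2181 and 2313 without the first or second B7-2 array, and 2142 without the first BTNL2 array. The share of higher calls never moved by over 10 percentage points under the settings run.

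Same-numbered arrays did not deviate together, with correlations across genes of -0.0641, -0.000967 and -0.0272 for the 3 pairs of groups. With 2 arrays per group these values cannot exclude a small batch shared by same-numbered arrays. With the replicate block, 3765, 3160 and 4827 genes and 11, 13 and 12 lists were called, and 62.7% of changes were opposed. The block ended the calls of 4 named results, Fen1, Uqcrfs1 and Ndufa6 for BTNL2 and Il2 for the third comparison. With the mean of all probe sets of a gene, Il2ra (-0.32) and Cd4 (-0.41) were called lower with BTNL2, and Il2ra (-0.33) also in the third comparison. Of the 223 called named results, 32 moved by over 1.5-fold under this setting, and 7 with 1 array left out, which were Tgfb3 for B7-2 and Slc17a6, Serpinf1 and Cdh1 in both BTNL2 comparisons; the other settings moved 0 by as much. Averaging the probe sets shrank 7 results to under 0.5 of their log2 change: for BTNL2 Nt5e from 2.23 to 0.85, Nr4a3 from 2.08 to 0.70, Insr from -1.29 to -0.58, Il6st from 0.72 to 0.30 and Tyms from 0.40 to 0.15, and for B7-2 Lif from 1.51 to 0.65 and Pde1a from 2.86 to 1.37. Inhba moved from -5.02 to -2.55. Il6st and Tyms were then not called. This setting averages bright and dim probe sets. Signal over background limits the fold of genes such as Xcl1, which read 6.8 in the B7-2 wells against control medians of 3.68 to 4.49.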

Other observations

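The gene families in the first paragraphs were chosen after the comparisons had been seen, as were the tests of Ifng and of the B7-2 arrays. Xcl1 and Ccl1 belong to the chemokine ligands and Ifi205 to the p200 family. All were already known as large rises with BTNL2, so the tests of these families are not independent support. The guanylate-binding proteins, aminoacyl-tRNA synthetases, killer cell lectin-like receptors and TNF superfamily ligands share members with lists tested above. Their tests are therefore not independent support either. The p-values were adjusted over the 12 families tested in a comparison, of which not all are described here. Of 7 guanylate-binding protein genes, 0 rose and 6 fell with B7-2 (median log2 change -1.36; camera adjusted p = 0.000184, and adjusted p = 0.176 with an estimated correlation), and 6 rose and 1 fell with BTNL2 (median 1.34; camera adjusted p = 1.54e-05, and adjusted p = 0.144 with an estimated correlation). Both changes use the same B7-2 arrays with opposite signs. In the BTNL2 wells against anti-CD3 alone, 2 of these 7 genes were higher and 1 lower (median -0.03, camera adjusted p = 0.853). The 14 MHC class I genes did not reverse between the B7-2 and BTNL2 comparisons. With B7-2, 0 rose and 6 fell (camera adjusted p = 0.00528, and adjusted p = 0.176 with an estimated correlation). With BTNL2, 2 rose and 3 fell (camera adjusted p = 0.926). Of 6 genes of the p200 family, DNA sensors and their relatives, 4 rose with BTNL2 (median 3.58; camera adjusted p = 1.87e-05, and adjusted p = 0.221 with an estimated correlation), with Ifi203 15.7-fold and Ifi209 24.2-fold higher. Of 9 type I interferon genes, 0 were called by limma with BTNL2 and 0 had an unadjusted p under 0.05, and Ifnb1 read 10.6 with B7-2 and 11.7 with BTNL2, near background. Of 15 TNF superfamily ligands, 8 rose and 0 fell with BTNL2 (camera adjusted p = 0.00197, and adjusted p = 0.221 with an estimated correlation), with Tnfsf11 (RANKL) 3-fold, Ltb 2.94-fold and Tnfsf10 (TRAIL) 2.78-fold higher.

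Of 17 genes of cytosolic aminoacyl-tRNA synthetases, 14 rose and 0 fell with B7-2 (median 0.55; camera adjusted p = 1.02e-08, and adjusted p = 0.176 with an estimated correlation), and 0 rose and 8 fell with BTNL2 (median -0.34; camera adjusted p = 1.54e-05, and adjusted p = 0.221 with an estimated correlation), with Lars 1.84-fold and Sars 1.73-fold lower. Of 33 chemokine ligand genes, 9 rose and 2 fell with BTNL2 (camera adjusted p = 0.0032, and adjusted p = 0.144 with an estimated correlation), although the median log2 change was only 0.11, with Cxcl10 3.91-fold and Ccl9 2.68-fold higher and Ccl4 1.5-fold lower. Of 19 killer cell lectin-like receptor genes, 7 rose and 1 fell with BTNL2 (camera adjusted p = 0.00045, and adjusted p = 0.144 with an estimated correlation), with Klra5 5.78-fold and Klrk1 5.22-fold higher.

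Cd8a, Eomes and Xcl1 were higher in wells that started from selected CD4 cells. One candidate explanation is a larger share of CD8 T cells, since bead selection leaves some: Cd8b1 would then rise with Cd8a, and its log2 change was 1.31 against 3.08 for Cd8a, below but within 2 standard errors of the 1.54 set as the limit. Against anti-CD3 alone, for which no limit had been set, Cd8b1 was not called (log2 change 0.43 ± 0.15, limma adjusted p = 0.0702). Cd8a changed there by 1.62 ± 0.10. Another candidate explanation is a larger share of NK cells: the median log2 change of 7 NK receptor genes was 0.308 with a standard error of 0.52, and 3 of the 7 were higher, Klrk1, Klrc1 and Klrd1, which CD8 T cells also transcribe, while Ncr1 read 5 and 6.19, near background. Neither can be told apart from a change within CD4 cells, because 1 gene and few receptors decide. The biological explanation, that BTNL2 changed the CD4 cells, is untested. Other types of T cell were not tested either. Trgv1, the only T cell receptor gamma gene analysed, was also higher with BTNL2 (log2 change 5.63).

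Interferon-stimulated genes were higher in the BTNL2 wells. If they followed the Ifng mRNA level, they would also rise with B7-2, which raised Ifng 4.78-fold. Their median log2 change there was -0.56, so they did not follow Ifng mRNA in that comparison. Interferon protein was not measured. Ifng also rose with BTNL2 (log2 change 1.11), so a part of it in the BTNL2 wells stays open. If myeloid cells carried these transcripts, myeloid markers would rise, and their median log2 change with BTNL2 was 0.0122 with a standard error of 0.145. Of the 21 markers 15 were not called, 5 rose and 1 fell. Their mean was 0.19, and fry called the list (adjusted p = 0.0145). A median over mostly unchanged markers cannot show a small share of such cells. Myeloid cells therefore stay open as carriers. Siglech, a marker of plasmacytoid cells, was not analysed here. Plasmacytoid cells left after the bead selection therefore stay open, as do a few cells that release interferon without adding much RNA. Material in the BTNL2 protein preparation and an effect of BTNL2 on the T cells also stay open, the last as untested.

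Genes changed by B7-2 tended to move the opposite way with BTNL2. Chance values of the B7-2 arrays, which enter both comparisons, were tested by using a different B7-2 array in each. The covariance of the log2 changes was then -0.0486 on average (-0.0528 and -0.0444 for the 2 ways of assigning the arrays), against -0.00226 as the lowest simulated with unchanged BTNL2 wells, which argues against chance values of single arrays as the whole of it. A difference common to both B7-2 wells could give the same covariance and stays open, as does an effect of BTNL2 that opposes costimulation.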
